A study of Drosophila melanogaster with 4 samples.

How the data were processed

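Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos of the wild-type Oregon-R strain, aged 14 to 16 h. The antibody, named BEAF-HB in the labels, is an affinity-purified rabbit polyclonal raised against residues 88 to 282 of the BEAF protein. BEAF (boundary element-associated factor) is a DNA-binding protein of chromatin domain boundaries. The labels write its second target isoform once as BEAF32B and once as BEAF42B. Per the labels' protocols, embryos were fixed in 1.8% formaldehyde. The series has 4 samples, 2 of ChIP DNA and 2 of input DNA, and samples were grouped by their titles. The free-text description of ChIP replicate 1 reads as input DNA, and that of input replicate 1 carries the antibody text. Titles were followed in both cases, and the deposited region lists belong to the 2 samples titled ChIP. Nothing in the labels says whether the 2 ChIP replicates came from separate embryo collections.

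The authors deposited 3 lists of regions, 1 for each ChIP replicate and 1 for the combined replicate set. Each row has a chromosome, a start, an end, a type (significant enrichment or significant depletion) and a score. Per the file headers, coordinates refer to FlyBase release 5, and the headers give the length of every sequence. Bowtie 0.12.7 is named in the submitters' processing notes. The peak caller, its thresholds, the way replicates were combined and the definition of the score are not given in the sources used here. The score is a value per region made by the authors, above 0 for regions typed as enriched and below 0 for those typed as depleted, and its scale and log base are not stated. It was therefore used only to describe, rank and filter regions within a list. All coordinates of the combined list are even numbers, against 26.1% of replicate 1 regions and 24.1% of replicate 2 regions with both ends even. The files give no read counts, so the sequencing depth is unknown. Intervals on shares and densities cover counting of regions only.

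Regions were read as 1-based inclusive intervals. Overlap meant at least 1 bp shared, and the midpoint stood for the position of a region because the files give no summit. Chance was estimated from 1000 seeded placements of a list, in which the regions of each sequence were put at random places of that sequence without overlapping each other and with their widths kept. The smallest p such a one-sided test can give is 0.001. Densities carry exact 95% Poisson intervals and shares exact (Clopper-Pearson) 95% binomial intervals. Region counts on the 6 chromosome arms (X, 2L, 2R, 3L, 3R and 4) were compared with arm length by two-sided exact binomial tests, Benjamini-Hochberg adjusted over the 6 arms. Since neighbouring regions are not independent draws, the 5 large arms were also compared with counts in 100-kb bins, reassigned 100000 times at random among arms (a two-sided permutation test), and intervals on ratios came from 2000 bootstrap draws of bins. Bins were reassigned and drawn 1 at a time, so unevenness over stretches longer than 100 kb was not preserved. These tests are over regions or bins of a list and not over samples. With 2 replicates no test across samples was made. Some results are given for the combined list only.

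The rule for naming regions, fixed before the data were examined, took the 20 regions with the highest score in the combined list that overlap a region in both replicate lists. The design also fixed comparisons with transcription start sites, genomic features, the BEAF sequence motif, 21 gene lists and the orientation of gene pairs. They were not run because neither a sequence nor an annotation of release 5 was used here. The table of gene names at hand refers to another assembly (Release 6 plus ISO1 MT), and no coordinate was taken from it or converted. Regions are therefore identified by position and carry no gene names. Alternatives were the 50% of each list with the higher score, a reciprocal overlap of 50%, each replicate's own list in place of the combined one, only the combined regions found in both replicates, and random placement between the first and last region of a sequence. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The overlap calculation was tested on simulated data made from the 4068 regions of replicate 1 on the 6 arms. Lists that kept 0, 50.2 and 89.8% of those regions overlapped 17.1, 54.5 and 90.0% of them, the excess being chance overlap.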

Results

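BEAF-bound chromatin was mapped in wild-type Drosophila embryos of 14 to 16 h, a stage at which organs are differentiating. The data compared are the regions enriched in 2 ChIP replicates and in the combined replicate set. The combined list held 5003 enriched regions, replicate 1 held 4169 and replicate 2 held 4349, with a replicate mean of 4259 ± 127 (SD, n = 2). The combined regions covered 12.8 Mb, and 97.3% of them lay on the 6 chromosome arms, where they took up 10.4% of the sequence. The median width was 2339 bp in the combined list, 2384 bp in replicate 1 and 2411 bp in replicate 2. These widths are far larger than a single protein-binding site, so a region marks a neighbourhood of binding and not a base-level position. The 2 input libraries have no region list of their own here, so no background level was measured in them separately.

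The regions with the highest authors' scores were found at the same places in both replicates. The highest-scoring region of all 3 lists lay on chromosome arm 3R, at 1472900 to 1476188 in the combined list (release 5, as are all coordinates here), with a score of 5.10. A second region among the 20 highest lay close by on 3R, at 1483676 to 1487768, with a score of 4.61. On 2R the highest-scoring region was at 17388068 to 17390850 (4.95), followed by 7854900 to 7859236 (4.84) and 8755408 to 8758868 (4.81). On X it was at 5630718 to 5633354 (4.89), and the next was at 11017340 to 11020386 (4.73). On 3R, 24887356 to 24890842 scored 4.86, 7787302 to 7790138 scored 4.70 and 20947164 to 20950914 scored 4.69. On 2L, 6966082 to 6969526 and 8363430 to 8367652 both scored 4.78. On 3L the highest-scoring region was at 20293994 to 20297178 (4.73), and 539330 to 542008 also ranked among the 20 highest (4.61).

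The 20 named regions comprised 6 on 2R, 6 on 3R, 3 on 2L, 3 on X and 2 on 3L. They were between 2637 and 4337 bp wide. In replicate 1 their counterparts ranked no lower than 27 of 4169 regions by score. In replicate 2, 19 of the 20 ranked within the first 100 of 4349. The exception was the 2L region at 8363430 to 8367652, which ranked 9 in replicate 1 and 124 in replicate 2, where the overlapping region started further upstream, at 8361367. All 20 highest-scoring combined regions overlapped a region in both replicate lists. What the annotation places at these positions was not analysed here.

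Binding regions were shared by the 2 replicates far beyond chance. Of the replicate 1 regions, 3958 of 4169 (94.9%, 95% exact binomial interval 94.2 to 95.6) overlapped a region of replicate 2. Of the replicate 2 regions, 3915 of 4349 (90.02%, 89.1 to 90.9) overlapped a region of replicate 1. Random placement of the other list gave 18.0% and 17.2% on average and at most 19.8% and 19.1% (one-sided permutation of positions, p = 0.001 for both, the smallest that 1000 placements can give). Among 3812 regions matched one to one, the midpoints differed by a median of 34.5 bp, and none had identical coordinates in both lists. The replicate 2 region was the wider one in 75.8% of these pairs, and the median difference in width over all pairs, replicate 2 minus replicate 1, was 70 bp, so the 2 lists differed slightly but steadily in width.

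Regions that were not shared had low scores. In replicate 1, every one of the 1042 regions in the highest score quartile overlapped a region of replicate 2 (lower limit of the 95% exact binomial interval 99.6%), whereas 81.6% (79.1 to 83.9) of the 1043 in the lowest quartile did so. In replicate 2 all 1087 regions of the highest quartile were shared, against 64.2% (61.2 to 67.0) of the 1088 in the lowest. Of the 211 replicate 1 regions and 434 replicate 2 regions without a counterpart, 192 and 390 respectively were in the lowest quartile of their own list.

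Scores fell into a large low-scoring group and a smaller high-scoring group. In the combined list the fullest score bin was 0.25 to 0.5, with 1089 regions. Counts fell to 144 in the bin from 1.75 to 2 and rose again to 221 in the bin from 3 to 3.25. Both replicates had the same shape, with a minimum in the bin from 2 to 2.25 (147 regions in replicate 1 and 136 in replicate 2). The second maximum held 207 regions in replicate 1 and 231 in replicate 2. Higher-scoring regions were wider, from a median of 1719 bp in the lowest score quartile of the combined list to 2943 bp in the highest (Spearman's rho = 0.81 across 5003 regions, permutation p = 1e-05, the smallest that 100000 resamples can give). Regions of a list are not independent replicates.

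**Figure D1:**
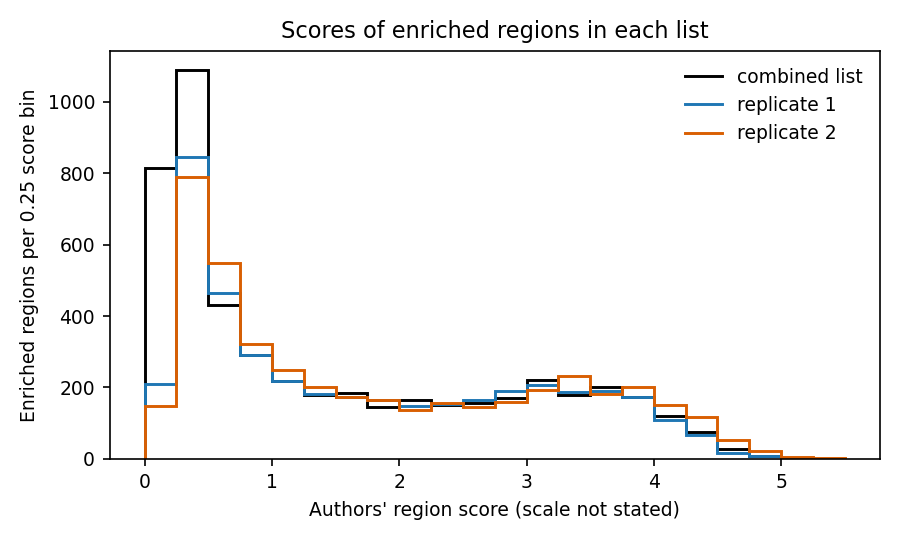
Number of enriched regions (y axis) by the authors' score in bins of 0.25 (x axis, scale not stated), with a line for the combined list, replicate 1 and replicate 2. All 3 lists show a large group below a score of 1 and a second, smaller maximum between 3 and 3.5.

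The combined list added regions to those of the replicates rather than keeping only the shared ones. Of its 5003 regions, 3892 (77.8%, 95% exact binomial interval 76.6 to 78.9) were found in both replicates, 606 (12.1%) in 1 replicate and 505 (10.1%) in neither. Regions in both had a median score of 1.53 in the combined list, against 0.209 for those in 1 replicate and 0.274 for those in neither. The combined list in turn held 99.7% of replicate 1 regions and 99.3% of replicate 2 regions. The 14 replicate 1 and 31 replicate 2 regions without a combined enriched region had scores of at most 0.406 and 0.567 in their own lists.

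BEAF regions were not spread over the chromosome arms in proportion to length. X had the highest density of the 5 large arms, with 1081 regions or 48.2 per Mb (95% Poisson interval 45.4 to 51.2), and 2R followed with 959 or 45.4 per Mb (42.5 to 48.3). The lowest densities were on 2L, with 777 regions or 33.8 per Mb (31.4 to 36.2), and on 3L, with 890 or 36.3 per Mb (33.9 to 38.7). 3R had 1098 regions or 39.4 per Mb (37.1 to 41.8). The small, largely heterochromatic chromosome 4 had 64 regions or 47.3 per Mb (36.5 to 60.5).

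Relative to arm length, X held 1.19 times and 2R 1.12 times the expected number, and 2L held 0.83 times and 3L 0.90 times (two-sided exact binomial test, Benjamini-Hochberg adjusted p = 2.3e-09, 0.00024, 3.4e-08 and 0.00035). The counts on 3R (0.97 times, adjusted p = 0.31) and on chromosome 4 (1.17 times, adjusted p = 0.24) did not pass the same exact test, although for chromosome 4 the interval leaves room for both lower and higher densities. Replicate means followed the same order of the large arms, with 40.5 ± 1.04 regions per Mb on X, 39.1 ± 1.20 on 2R, 34.1 ± 1.44 on 3R, 30.7 ± 0.951 on 3L and 28.8 ± 0.430 on 2L (SD, n = 2). In 100-kb bins, X averaged 4.82 regions and the other 4 large arms together 3.86, a ratio of 1.25 (95% bootstrap interval 1.13 to 1.38, permutation p = 0.00013). The ratio was 1.23 in replicate 1 and 1.22 in replicate 2 (permutation p = 0.00092 and 0.0014). Each large arm was also set against the other 4 in these bins. The ratio was 1.15 on 2R and 0.88 on 3L (permutation test, Benjamini-Hochberg adjusted p = 0.020 for both), weaker evidence than by the exact test. By the same permutation test it was 0.81 on 2L (adjusted p = 0.00035) and 0.97 on 3R (adjusted p = 0.53). The excess on 2R did not pass the test among the 50% of combined regions with the higher score (1.07 times, exact binomial test, adjusted p = 0.12).

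**Figure D2:**
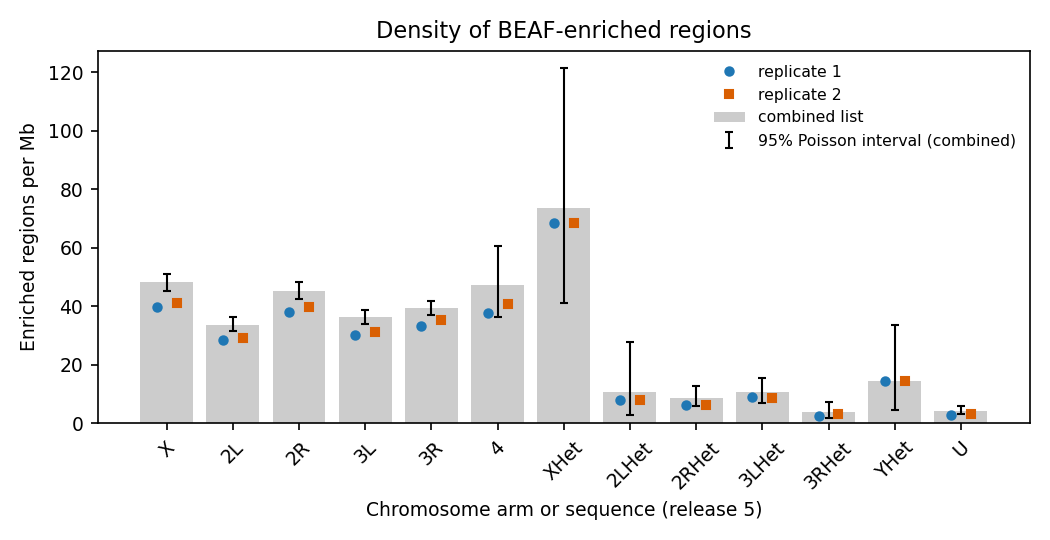
Enriched regions per Mb (y axis) on each chromosome arm and unplaced or heterochromatic sequence of release 5 (x axis). Bars give the combined list with its 95% Poisson interval, circles replicate 1 and squares replicate 2. X and 2R stand above 2L and 3L in all 3 lists, and most heterochromatic sequences lie below 15 per Mb.

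The 6 assembled sequences labelled as heterochromatin carried few regions, apart from the short XHet sequence. Chromosome 4, at 47.3 regions per Mb, is not among them and is counted with the arms. The 6 heterochromatic sequences together held 90 regions on 9.28 Mb, or 9.70 per Mb (95% Poisson interval 7.80 to 11.9), against 40.5 per Mb (39.3 to 41.6) on the 6 arms. XHet stood apart with 15 regions on 0.204 Mb, or 73.5 per Mb (41.1 to 121), and 14 regions in each replicate. YHet had 5 regions in all 3 lists, with a median score of 2.84 in the combined list. The lowest heterochromatic density was on 3RHet, at 3.97 per Mb (1.90 to 7.30), and the unplaced sequence U had 4.38 per Mb (3.18 to 5.88). Uextra, a collection of unplaced fragments, held no region in any list, and whether it was searched is not stated. How the authors treated reads that match repeated sequence is also not stated, and that handling could lower or raise these counts.

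BEAF regions were clustered along the sequences relative to random placement, which took no account of mappability or gene density. Midpoints of neighbouring combined regions on all sequences were a median of 10524.5 bp apart, against 18103 bp in random placements, of which none was below 17385 bp (one-sided permutation of positions, p = 0.001, the smallest possible). On the 6 arms alone, a restriction chosen after the data were seen, the median was 10367 bp over 4863 pairs, against 17722 bp at random and none below 17073 bp (permutation p = 0.001). The share of neighbours less than 10000 bp apart, a distance also chosen after the data were seen, was 48.4% on all sequences against 28.4% at random. The medians were 12112 bp in replicate 1 and 11731 bp in replicate 2, each also with permutation p = 0.001. The planned threshold of 2000 bp took in only 0.641% of neighbours, since most regions are wider than that. This share exceeded the random 0.257% in the combined list (permutation p = 0.001). It was 0.277% in replicate 2, against 0.101% in random placements of that list (permutation p = 0.001), and 0.192% in replicate 1, against 0.100% at random, where the test was not passed (permutation p = 0.053). With only the regions found in both replicates the share was 0.0516% of 3879 pairs, against 0.00928% at random (permutation p = 0.046). The shares in the replicates and in these shared regions rest on few pairs. In the 50% of combined regions with the higher score the share was 0%, against 0.00137% at random, too little for the test to show clustering.

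Of the 12 longest stretches without a region on the arms, 4 lay on 2L, 4 on 3L, 3 on X and 1 on 2R. The longest was 478 kb on 2L, at 15772399 to 16250455, followed by 456 kb on 2L, at 16911147 to 17366977, and 402 kb on 2R, at 15559147 to 15960725. These 3 were longer than 375 kb, the longest gap in any of 1000 random placements, which likewise took no account of mappability or gene density. Neither replicate had an enriched region lying wholly inside any of the 12. The combined list holds 99.7% of replicate 1 and 99.3% of replicate 2 regions, so this is hardly independent support. Over 118 windows of 1 Mb, the variance of the count was 3.67 times its mean, and in random placements at most 1.77 times. The sparsest window was 14000001 to 15000000 on 2L, with 10 regions (6 in replicate 1 and 5 in replicate 2), and no window in the random placements of the combined list had fewer than 14. The densest had 67 regions each and were 5000001 to 6000000 on 3R and 11000001 to 12000000 on X. Such counts did not exceed the highest random one, 73.

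**Figure D3:**
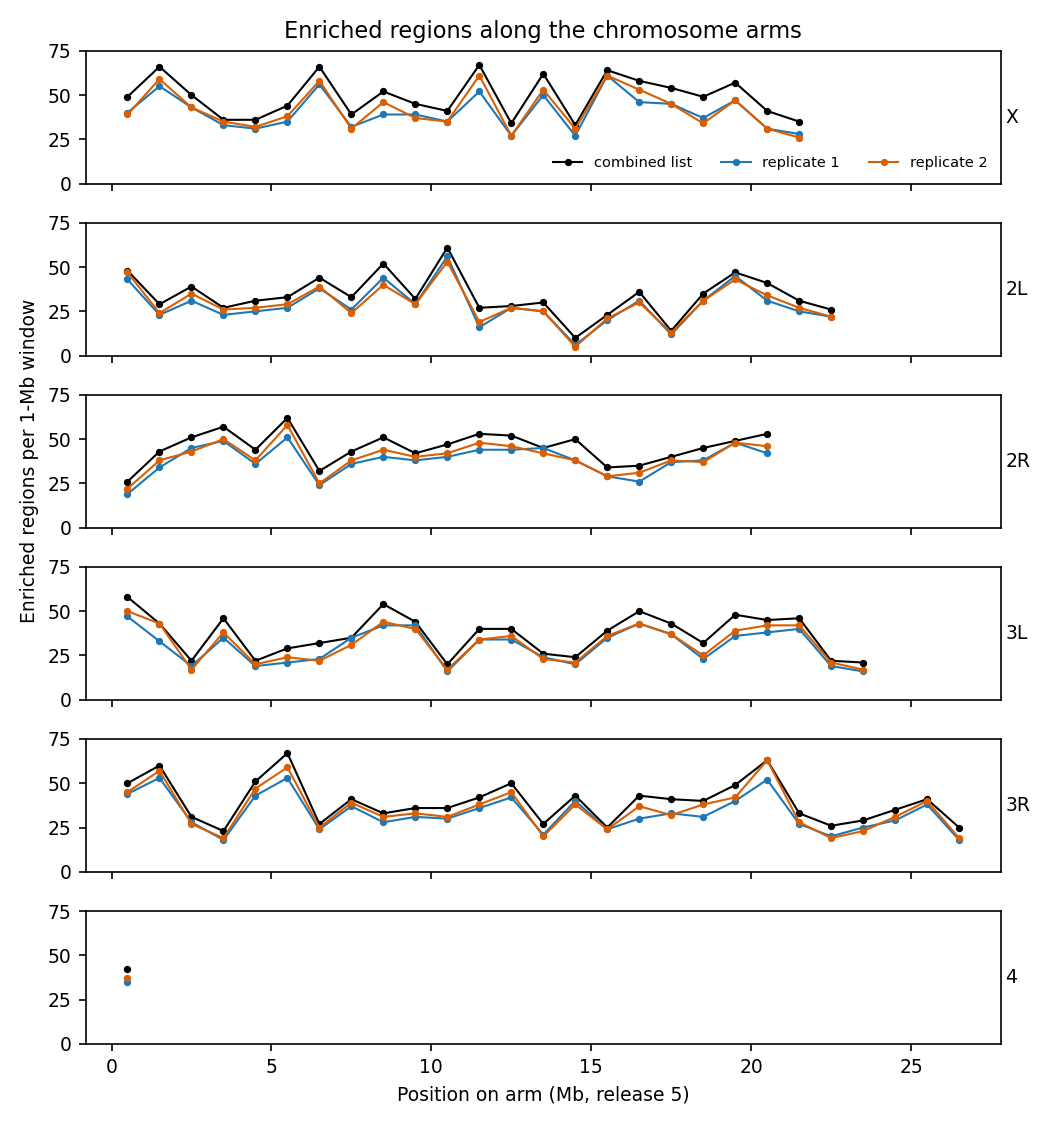
Enriched regions per 1-Mb window (y axis) along each chromosome arm (x axis, Mb in release 5), 1 panel per arm, for the combined list (black), replicate 1 (blue) and replicate 2 (orange). The lists rise and fall together, with the deepest minimum, 10 combined regions, on 2L between 14 and 15 Mb.

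Wide regions were more frequent on X. Regions over 5000 bp made up 205 of the 5003 in the combined list, all 205 overlapped regions in both replicates, and 57 of them covered several separate regions of a replicate. On X they were 74 of 1081 regions (6.85%), against 125 of 3724 (3.36%) on the other 4 large arms (odds ratio 2.12, two-sided Fisher's exact test p = 2.1e-06). The shares were 5.72% and 2.50% in replicate 1 (p = 7.1e-06) and 6.81% and 3.49% in replicate 2 (p = 2.6e-05) by the same exact test. This comparison was chosen after the data were seen, and its exact tests treat clustered regions as independent draws. The widest regions were 9048618 to 9059858 on X (11241 bp), 22405416 to 22416644 on X (11229 bp), 17544092 to 17555092 on 2R (11001 bp), 4823298 to 4834274 on X (10977 bp) and 7823898 to 7834368 on X (10471 bp).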

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

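Of the tests in this part, those on the depleted regions and on the scores of regions found in neither replicate were chosen after the result was seen. The combined list typed 23 regions as significantly depleted, a class that no comparison above uses. Each replicate list held 1 such region, on 2RHet in replicate 2 and on 3LHet in replicate 1, and both lay at combined depleted regions.

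The 23 depleted regions are mostly places that a replicate list calls enriched. They overlapped an enriched region of replicate 1 or replicate 2 in 19 cases, 11 with each replicate and 3 with both, against 2.88 on average and at most 9 in 1000 random placements (one-sided permutation of positions, p = 0.001, the smallest possible). An example is 2R 5801606 to 5803432, with a score of -0.0438 in the combined list, while the overlapping regions of replicate 1 (5801941 to 5803367) and replicate 2 (5801585 to 5803416) are typed as enriched, with scores of 0.106 and 0.117. Depleted scores ranged from -0.0654 to -0.000797, just under the lowest enriched score of 0.00112. The 19 overlaps argue against a loss of ChIP signal in both replicates as the source of the class as a whole, and are consistent with a type assigned by the sign of a score near 0. How the authors assigned the type remains open, as do the 4 regions with no counterpart in a replicate list.

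The 505 combined regions found in neither replicate list were weak, and many were narrow. Their median score stood at the 19.1 percentile of the combined list (95% bootstrap interval 17.5 to 20.5). The narrowest region was 1001 bp in the combined list and 1302 bp in the replicates, and 51.1% (95% exact binomial interval 46.6 to 55.5) of the 505 were narrower than 1302 bp. Of all 314 combined regions under 1302 bp, 56 still overlapped a replicate region. A smaller minimum width may account for part of the 505. Just over 50% of those listed were that narrow (258 of 505), and the interval includes 50%. Whether the smaller minimum width accounts for most of them is therefore undecided. The median of the 247 wider ones (0.188) stood at the 10.1 percentile (8.91 to 11.9), which is consistent with places near the calling threshold that pass only in the combined set. The 258 narrow ones scored higher (median 0.330, against an upper limit of 0.326 for the lowest quartile of the list), and their median stood at the 25.5 percentile (24.2 to 26.6). For them that explanation is undecided, since the interval includes the limit of the lowest quartile. The highest-scoring of all were 1348086 to 1349086 on chromosome 4 (3.18) and 7508850 to 7509850 on U (2.76).

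The higher density on X was weighed against technical explanations. Reassigning 100-kb bins among the large arms gave a difference as large with p = 0.00013 (two-sided permutation test). This argues against uneven spread within such bins alone. Stretches of up to 478 kb without a region span several bins, and reassigning single bins breaks them up. Uneven spread on that larger scale therefore remains open. The X to autosome ratio was 1.29 (95% bootstrap interval 1.12 to 1.46) in the 50% of regions with the higher score, against weak regions near the threshold as the cause. It was 1.28 (1.16 to 1.42) without the centromere-proximal 10% of each arm, against sparse proximal sequence on the autosomes as the cause. Gene density, the sexes of the embryos and differences in mappability between the arms remain open and were not tested, so the excess may still have a technical origin.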

How the results depend on the processing

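Of the 59 alternative values computed, 54 kept their direction and side of the threshold, or moved by less than their counting interval. They are not independent checks, since the alternatives reuse the same regions. Random placement between the first and last region changes only the random values and not the observed ones. The share of combined regions found in both replicates moved from 77.8% to 81.8% when only the 50% of each list with the higher score was used. That part holds fewer regions in the replicates (2084 and 2174) than in the combined list, which by itself keeps this share below 100%. Against the whole replicate lists, 98.8% and 99.8% of the combined regions in score quartiles 3 and 4 (the highest) were found in both. With the same restriction the 2R excess fell to 1.07 times (exact binomial test, adjusted p = 0.12). The share of neighbours under 2000 bp apart fell to 0%, but only 0.00137% was expected at random, so its fall shows nothing about clustering. When each replicate list took the place of the combined list (that is, without the other replicate), that share ranged from 0.192 to 0.277% (combined list 0.641%, against 0.257% at random). The lower value, in replicate 1, stayed above its own random mean of 0.100% but no longer passed (permutation p = 0.053), and the higher, in replicate 2, passed against 0.101% (permutation p = 0.001). The median spacing rose from 10524.5 to 18697.5 bp with the higher-scoring 50%, where fewer regions also raise the random value, to 35301 bp, and its permutation p stayed at 0.001. Restricting lists by score lowers the number of regions, and the cause of the lost calls on 2R and in replicate 1 was not tested further. The shares of regions shared between replicates ranged from 92.9 to 99.95% for replicate 1 and from 89.1 to 99.9% for replicate 2 over all alternatives, the highest being the higher-scoring part of 1 list against the whole other list, which was chosen after the data were seen. The count on 3R, not past the threshold in any setting run, went from 0.97 to 1.00 times expectation, just to the other side of it, with only the regions in both replicates. X, 2L and 3L stayed past the threshold in every alternative run. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no region list here. Other settings for start sites, features, motifs, gene lists and gene pairs were not run, since those comparisons were not made. Depth cannot be judged from the lists.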

Other observations

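Both tests in this part were chosen after the region lists had been read and before their own results were seen, except the bin bootstrap intervals and the adjustment of the first, which were added after its exact tests were seen. Density varied along the arms in a way that differed between them. In the centromere-proximal 10% of each large arm, 4 of the 5 arms had fewer combined regions per Mb than in the rest. The ratio of proximal to remaining density was 0.52 on 3L (49 regions, two-sided exact binomial test p = 1.8e-06), 0.59 on X (67 regions, p = 1.2e-05), 0.79 on 2R (77 regions, p = 0.041) and 0.91 on 2L (71 regions, p = 0.47), unadjusted over 5 arms. Benjamini-Hochberg adjusted over the 5 arms, 3L and X stayed past the threshold in the combined list and in both replicates by the exact test, while 2R did not in the combined list or in replicate 2 (adjusted p = 0.068 and 0.056) and did in replicate 1 (0.014). On 3R the ratio was 1.20 (129 regions, exact p = 0.056, adjusted 0.070), and by the same exact test it was 1.29 in replicate 1 and 1.24 in replicate 2 (p = 0.012 and 0.029, adjusted 0.014 and 0.048). The exact tests on 3R in the replicates count against a deficit shared by all 5 arms. They treat clustered regions as independent draws, however, and 95% bootstrap intervals over 100-kb bins for the 3R ratio included 1 in all 3 lists (0.88 to 1.54 in the combined list, 0.95 to 1.69 in replicate 1 and 0.89 to 1.61 in replicate 2). Because of this spread, whether 3R lacks the deficit is left open. The same bin intervals in the combined list lay below 1 on 3L (0.32 to 0.69), X (0.34 to 0.88) and 2R (0.56 to 0.997), and included 1 on 2L (0.63 to 1.22).

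A hypothesis was that regions cluster by strength, so that neighbours have similar scores. The Spearman correlation between scores of adjacent regions on the 6 arms was 0.0773 over 4863 pairs in the combined list, above every one of 1000 permutations of scores within arms, of which the highest was 0.0481 (one-sided p = 0.001). It was 0.0512 in replicate 1 (permutation p = 0.003) and 0.0346 in replicate 2 (permutation p = 0.027). The relation is in the predicted direction in all 3 lists and very small, and regions are not independent replicates. Regions of the lowest score quartile on the arms had another region, of any score, within 10000 bp in 62.4% of cases. In the quartiles above it the shares were 70.7, 76.25 and 77.2%, nearly level between the upper ones. These shares count neighbours of any score and do not bear on whether neighbouring scores are alike. A trend of the calling threshold along the chromosome may give either pattern.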
